A study of Mus musculus with 2 samples.

How the data were processed

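Single-cell RNA and CellPlex tag counts were analysed for CD45+CD11b+ cells of the dura mater of wild-type mice at 8 weeks of age, 2 days after retro-orbital injection of 50 µl of PBS (6 mice, 1 library) or of group B streptococcus (5 mice, 1 library). Per the labels, dura was peeled from the calvaria and digested with collagenase IV for 20 min at 37 °C, and 10750 cells per control mouse and 11600 per infected mouse were sorted and pooled. The stated pooled total of the infected library, 46400 cells, is 4 times the number per mouse, although the title and the tags give 5 mice, and all 5 tagged mice were analysed. The dose of bacteria is not printed because its exponent is ambiguous in the labels. The deposited matrices hold raw UMI counts of genes and tags for every listed barcode, whole numbers without a cell call, made by the authors with Cell Ranger 7.1 on mm10. The release of the gene annotation behind them is not given in the sources used here, and gene coordinates were taken from GENCODE M21.

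A cell was a barcode with at least 500 gene UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Of 1388903 control and 1631789 infected barcodes, 14557 and 12414 passed the UMI minimum, 14548 and 12408 the gene minimum and 14003 and 12342 the mitochondrial maximum. Each tag was called with a 2-component mixture, which set the lowest accepted tag count at 46 to 192 UMIs in control and 105 to 186 in infected mice. Exactly 1 tag was found in 9032 control and 9325 infected cells, no tag in 956 and 261, and at least 2 tags in 4015 and 2756 (28.7% and 22.3%). Scrublet (expected rate 0.1, run per library in scanpy) called 9.21% and 5.95% of cells, including 18.3% and 19.2% of cells with 2 or more tags. Cells with more than 1 tag, without a tag or with a Scrublet call were left out, since their mouse or their identity was open. Kept cells numbered 742 to 1683 per control mouse and 1600 to 1981 per infected mouse, with 3033113 to 8267447 and 7097716 to 14415817 UMIs per mouse.

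Counts were scaled to 10000 per cell, log-transformed, reduced to 2000 variable genes and 30 principal components, linked to 15 neighbours and clustered with Leiden at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12, seed 1). Clusters were named by the marker list with the highest score, which had to be at least 1.5 with at least 3 markers detected. Among the 10 leading genes the list needed at least 1 marker, no other list could have more, and a list of another lineage had to stay below 3. Clusters in which a second list came within 0.75 were first split by a second clustering (1000 variable genes, 15 components, resolution 0.5). Clusters with a median UMI count below that of the library holding most of their cells, divided by 3, were left unnamed. These naming, splitting and depth rules were revised over several rounds after clusters and shares had been seen and before any gene test was run. Classes are called X-like because identity rests on markers alone.

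Class shares were taken per mouse among kept cells and tested with an exact two-sided permutation of the difference of means over all 462 splits, with Benjamini-Hochberg adjustment over the named classes and, apart, over the unnamed clusters. Counts were summed per mouse and class for mice with at least 20 cells of the class and classes with at least 3 such mice per group. Classes tested were macrophage, classical monocyte, non-classical monocyte and cDC2 with all mice, and fibroblast with control mice 4, 5 and 6 and infected mice 1, 4 and 5. UMIs per mouse were 1182738 to 6020752 in macrophage-like, 157388 to 9475034 in classical monocyte-like, 70878 to 1774814 in non-classical monocyte-like, 197792 to 694298 in cDC2-like and 219514 to 584947 in fibroblast-like cells. Mature neutrophil-like cells were not tested for genes because only 2 control mice had 20 of them, and cluster 11 was left out because it had no cell type and low quality.

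Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (robust, TMM, filterByExpr, two-sided) in R 4.3.3, with group as the only term, and passed at a BH-adjusted p of 0.05. No batch term was possible because library and group coincide. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one, for lists of at least 3 measured members, and with fry. The lists were type I interferon, interferon gamma, MHC class I, MHC class II, inflammatory cytokines and NF-kB targets, bacterial recognition, antimicrobial and acute-phase effectors, resident dural macrophage identity, complement, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, iron handling, leukocyte adhesion, arginine and polyamine metabolism, phagocytosis and lysosome, dissociation stress, unfolded protein response, haemoglobin, sex-linked, mitochondrial and ribosomal protein transcripts. Marker lists, gene lists, filters, tests, the rule for named genes and the alternative settings planned at that stage were written before the data were examined. The list minimum of 3 members and the use of log2(CPM + 10) for spotting single mice were set after it. Differences between classes in list response were tested by exact permutation on the difference within mouse of mean log2(CPM + 10). Macrophage against mature neutrophil, planned, was not run because 2 control mice had enough of both, and macrophage against non-classical monocyte and against cDC2 were added in its place.

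Named genes were the 10 largest rises and 10 largest falls per class (5 each for cDC2 and fibroblast) among genes that passed, with at least 20 TMM-normalised CPM in the higher group, no overlap between the mice of the groups, an ambient limit of at most 25% and no placeholder symbol. Up to 4 passing members of each list with at least 20 CPM were added for the 3 classes with most cells. Some genes that met the rule are not reported here. Where a group held 0 UMIs of a gene, the fold is a lower bound with 3 counts put in for 0, and with 1 to 3 UMIs the ratio carries a 95% counting interval. Such intervals cover counting only, not the spread between mice. Ambient profiles came from barcodes with at most 100 gene UMIs (5146875 and 5549516 UMIs), and limits from the lowest class-to-ambient ratios among 100 abundant ambient genes.

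The alternatives were a UMI minimum of 1000, a mitochondrial maximum of 5%, Scrublet calls kept, a fixed tag margin of 10 UMIs and 3-fold, Leiden resolution 0.5, shares with tags ignored, each mouse left out in turn, DESeq2 1.42.0 size factors or its Wald test, no low-count filter, ambient counts subtracted, at most 100 cells per mouse and class, an estimated correlation, CPM + 1 and an ambient profile of at most 50 UMIs. Added after the data were seen were low-UMI clusters named by their markers or left out of the denominator, mixed clusters not split, macrophages without cluster 8 or with the unnamed proliferating cluster, cDC2 without their proliferating cluster, and the added class pairs with Scrublet calls kept or without cluster 8. The planned settings for libraries without mice were not needed. A single list was followed through the alternatives only if it passed.

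The gene test was tested on simulated data with the sizes and dispersion of each class. In each class 200 genes were changed, drawn only from genes with an expected count above 5 in the smallest mouse sum. Far more genes passed in the real data (5028 in macrophage-like cells), so the rates below hold for the simulated setting only. Of 100 genes raised or lowered 2-fold, 84% were found in macrophage-like, 79% in classical monocyte-like, 92% in non-classical monocyte-like, 73% in cDC2-like and 12% in fibroblast-like cells, and at 4-fold 99%, 96%, 93%, 94% and 70%. Between 5 and 17 unchanged genes per class were called. Groups of mice were searched for a mouse apart with the Dixon rule at limits of 0.71 for 5 and 0.625 for 6 mice. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.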

Results

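Single-cell 3' gene expression was measured in CD45+CD11b+ cells sorted from the dura mater, the outer membrane around the brain, of 8-week-old wild-type mice. The mice had received PBS or group B streptococcus by retro-orbital injection 2 days earlier. Cells of each mouse carried a CellPlex oligonucleotide tag, so 6 control mice and 5 infected mice could be told apart within 1 control library and 1 infected library. The control library held 84012284 gene UMIs (unique molecular identifiers) over all barcodes and the infected library 89790939. After filtering, 8499 control cells with 38096739 UMIs and 9135 infected cells with 54893908 UMIs were kept. The median cell had 4067 UMIs and 1693 genes in the control library and 4827 UMIs and 1827 genes in the infected one. Control mice gave 742 to 1683 cells each, infected mice 1600 to 1981. Infected mouse 5 was the shallowest of its group, with a median of 2397.5 UMIs per cell. Median mitochondrial content per cell was 2.53% in control and 0.798% in infected cells. Infection and library were the same split, so a library effect could not be separated from infection, and the p-values measured only the spread between mice inside libraries. Genes are given by symbol with coordinates on genome build mm10 taken from GENCODE M21, and every gene with printed coordinates is protein_coding.

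The first question was how infection changed the myeloid makeup of the dura. Monocyte-like and mature neutrophil-like cells rose and macrophage-like cells fell as shares of the kept CD45+CD11b+ cells with at least 500 UMIs. Cell numbers per dura are not known from these data, so a lower share need not mean fewer macrophages. Macrophage-like cells fell from 44.8% ± 5.31 (SD, n = 6 mice) to 13.7% ± 5.36 (n = 5), and every infected mouse lay below every control mouse. Classical monocyte-like cells, defined by markers such as Ly6c2 and Ccr2, rose from 3.26% ± 1.70 to 25.8% ± 14.7. Mature neutrophil-like cells rose from 1.37% ± 0.546 to 15.1% ± 10.8. For these 3 classes the exact two-sided permutation p was 0.00217 each, the smallest possible over 462 splits, and the BH-adjusted p was 0.00794. Non-classical monocyte-like cells rose from 2.01% ± 0.646 to 6.06% ± 3.65 (exact permutation p = 0.00433, adjusted p = 0.0119). With low-UMI clusters named by their markers macrophage-like cells were 77.4% and 27.9% (difference −49.54), and outside those clusters 69.1% and 20.7% (−48.36). The first of these settings still left low-UMI clusters 7 (29 control and 1010 infected cells) and 13 (185 and 292) unnamed. Macrophage was the best list of both, but their cells, mostly infected, were not counted as macrophage-like. The non-classical monocyte difference of 4.05 was 2.59 without infected mouse 4, 2.28 at Leiden resolution 0.5 and 10.42 with mixed clusters not split. The infected mice differed among themselves. Mature neutrophil-like cells made up 24.6%, 22.9% and 21.1% in mice 1 to 3 but 4.22% and 2.45% in mice 4 and 5, while non-classical monocyte-like cells were highest in mice 4 and 5, at 11.9% and 6.99%.

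The remaining classes did not pass correction. Osteoclast-like cells were 0.460% ± 0.315 of control and 0.0737% ± 0.0578 of infected cells, and migratory DC-like cells 0.564% ± 0.163 and 1.21% ± 0.676 (exact permutation p = 0.0368 and adjusted p = 0.0675 for both, n = 6 and 5). cDC2-like cells were 3.65% ± 1.17 and 2.17% ± 1.39 (exact permutation adjusted p = 0.136), neutrophil progenitor-like cells 0.152% and 0.461% (0.182), and immature neutrophil-like cells 1.99% and 1.36% (0.323). Fibroblast-like cells, which lie outside the CD45+CD11b+ gate, were 1.67% and 1.74%, with an exact permutation p of 0.898. Endothelial-like cells were 0.141% and 0.123% (exact permutation adjusted p = 0.845). Clusters with low UMI counts, left without a cell type, held 35.2% ± 3.17 of control and 28.3% ± 13.6 of infected cells (exact permutation p = 0.232, n = 6 and 5). Of the other unnamed clusters, cluster 11 held 4.01% and 2.27% (adjusted p = 0.0541), a small proliferating cluster 0.0542% and 0.515% (0.168), cluster 19, led by Gzma and Mcpt4, 0.393% and 0.723% (0.267), and cluster 20 0.241% and 0.452%, all from exact permutation.

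**Figure D1:**
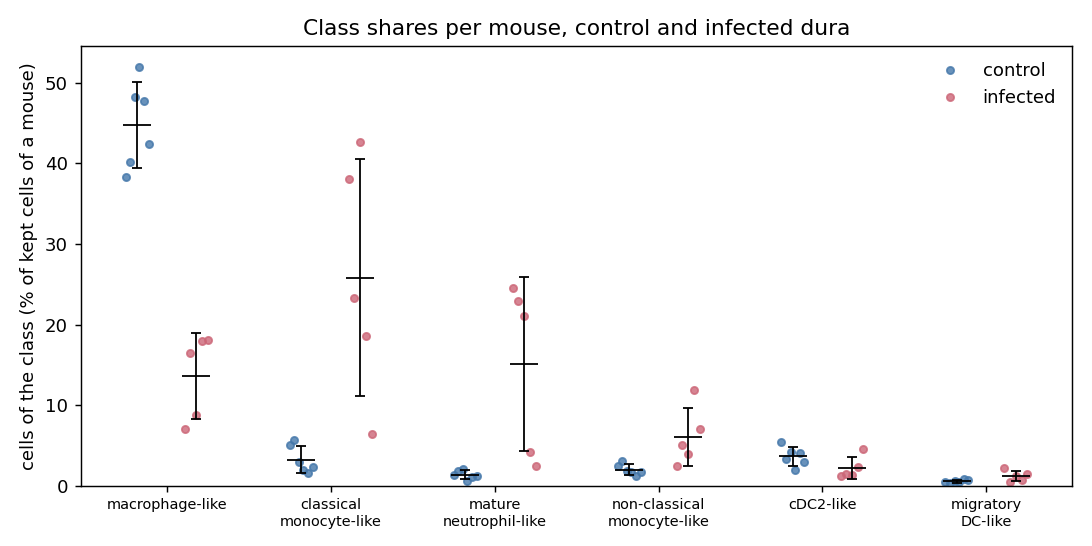
Share of 6 cell classes in the kept cells of each mouse (y axis, %), points being mice and bars the mean with SD, for 6 control and 5 infected mice. The mean share of macrophage-like cells dropped from 44.8% to 13.7%, while that of classical monocyte-like cells rose from 3.26% to 25.8%.

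The macrophage-like, monocyte-like, mature neutrophil-like and immature neutrophil-like classes were formed mainly by different clusters in the 2 groups. Control macrophage-like cells came mainly from clusters 1 (1686 control and 14 infected cells), 6 (1090 and 2) and 8 (878 and 128, high in MHC class II genes). Infected ones came mainly from cluster 4 (94 and 1074), whose leading genes included Ccl8, Ccl12 and Saa3 and also the resident macrophage genes Cd163 and Lyve1. The separation of the clusters and the gene changes are therefore the same signal. Classical monocyte-like cells came from clusters 14.2 (155 and 2) and 14.3 (74 and 0) in control mice. In infected mice they came from clusters 3 (0 and 1388), 10 (1 and 619), 9.1 (0 and 243) and 9.5 (0 and 153). Non-classical monocyte-like cells came from cluster 14.1 (161 and 2) in control mice and from clusters 9.2, 9.3 and 9.4 (210, 171 and 169 infected cells) in infected mice. Mature neutrophil-like cells came from cluster 16.2 (100 and 1) and cluster 2 (11 and 1380). cDC2-like cells of both groups shared cluster 15 (241 and 191), next to a proliferating cDC2 cluster (70 and 2).

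The second question was which genes and pathways infection changed within each class. In macrophage-like cells, acute-phase, interferon-stimulated and inflammatory genes rose, and genes of resident macrophages fell. Of 10630 genes tested with edgeR, 2582 rose and 2446 fell, 732 and 551 of them by at least 2-fold. Saa3, a serum amyloid A gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), rose from 0.165 ± 0.216 CPM (SD, n = 6) to 8034 ± 8209 (n = 5). Its log2 fold change was 15.25 ± 1.52 (SE; adjusted p = 3.5e-05), from 4 UMIs in all control to 57076 in all infected macrophage-like cells. Acod1, whose enzyme makes itaconate (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573, plus strand), rose by 6.58 ± 0.89 log2 units from 3.11 to 231 CPM. Slfn4 (6.26), Spon1 (5.66), Lcn2 (5.45; 10.7 to 481 CPM), the interleukin-1 antagonist gene Il1rn (5.43), Clec4e (5.27), Jaml (5.13) and Mrap (5.09) followed. Ambient RNA could account for at most 4.11% of infected Saa3, but for 14% of Slfn4 and Lcn2.

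Among falling genes of macrophage-like cells, Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand) had the largest change, log2 fold change −5.62 (adjusted p = 0.0044; 68.7 ± 67.5 to 1.12 CPM). Egfl7 fell by 4.57 log2 units (adjusted p = 2.1e-09). Ccl24, an eosinophil attractant (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049, minus strand), fell from 224 ± 48 to 12.7 ± 7.4 CPM, a log2 fold change of −3.99 ± 0.30. Pla2g2d (−3.97), Mmp9 (−3.81), Siglech (−3.77), Tslp (−3.51), Lpl (−3.38), Serpinf1 (−3.34) and Gimap6 (−3.20) also fell. No overlap between the mice of the groups was seen for 29.2% of the tested genes, where chance gives 0.433%, and 3082 of the genes that passed had none.

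Interferon genes of macrophage-like cells rose nearly without exception. In the type I interferon list 37 of 38 measured genes rose and 0 fell (37 and 0 adjusted over the list alone, median log2 fold change 2.12, camera adjusted p = 2.9e-20). In the interferon gamma list 27 of 29 rose and 0 fell (28 and 0 adjusted over the list alone, median 2.22, adjusted p = 1.3e-12), and in the MHC class I list 13 of 15 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.88, adjusted p = 4.1e-07). For all 3 lists the adjusted p was 0.27 with an estimated correlation in place of the preset one. Oasl1 (3.28; 33.6 to 319 CPM), Cxcl10 (3.21), Oas3 (2.81), Cd274 (4.72; the PD-L1 gene, 11.6 to 290 CPM), Gbp4 (4.69), Gbp6 (4.21) and Gbp5 (3.89) rose. So did Nlrc5 (2.37), Tap1 (1.91), H2-T22 (1.41) and H2-Q6 (1.38). Cxcl10 overlapped between the groups of mice.

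MHC class II genes of macrophage-like cells went the other way. In their list 2 of 11 genes rose and 8 fell (2 and 8 adjusted over the list alone, median −0.80, camera adjusted p = 0.048), with adjusted p = 0.414 with an estimated correlation and 0.0858 with fry. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823, minus strand) fell from 3966 ± 296 to 1763 ± 671 CPM (log2 fold change −1.17 ± 0.23, adjusted p = 0.0018), H2-Ab1 by 1.09, H2-Eb1 by 1.07 and Cd74 by 0.68 log2 units. Ctss was among the 2 genes of the list that rose. The list call depended on which macrophage clusters were counted. Cluster 8, an MHC-II-high cluster, made up 878 of 3854 control and 128 of 1220 infected macrophage-like cells. Without it, 2 genes rose and 2 of 10 fell (median −0.26, camera adjusted p = 0.86, in a range of 0.00127 to 0.981 over all alternatives). H2-Aa was then −0.65 (edgeR adjusted p = 0.0727, in a range of 8.6e-07 to 0.0886).

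Inflammatory and antibacterial genes rose in macrophage-like cells, the inflammatory ones not in every mouse. The inflammatory score of infected mouse 5, 6.48, lay within the control range of 6.33 to 6.49, while the other 4 infected mice were at 7.38 to 7.93. Of the inflammatory cytokine and NF-kB list 26 of 38 rose and 1 fell (27 and 1 adjusted over the list alone, median 1.12, camera adjusted p = 4.7e-06), and of the glycolysis and hypoxia list 19 of 27 rose and 2 fell (19 and 3 adjusted over the list alone, median 0.83, adjusted p = 0.0014). Both had adjusted p = 0.414 with an estimated correlation. Of the bacterial recognition list 21 of 33 rose and 4 fell (21 and 4 adjusted over the list alone, median 0.70, adjusted p = 0.000122), and of the antimicrobial and acute-phase list 15 of 25 rose and 4 fell (16 and 5 adjusted over the list alone, median 0.66, adjusted p = 0.0039). Both had adjusted p = 0.307 with an estimated correlation. Complement genes rose in 9 of 17 and fell in 1 (10 and 1 adjusted over the list alone, median 0.49, adjusted p = 0.0041), and leukocyte adhesion genes rose in 16 of 25 and fell in 4 (16 and 5 adjusted over the list alone, median 1.00, adjusted p = 0.0023). These 2 lists had adjusted p = 0.27 with an estimated correlation. The chemokine gene Ccl5 rose by 4.32 log2 units (adjusted p = 0.0056) and the scavenger receptor gene Marco by 5.03 (adjusted p = 0.018), both with overlap between the groups. Fcgr4 (3.68; 44.8 to 569 CPM), Clec4d (3.60), Cfb (4.15; 14.7 to 250 CPM), C6 (3.72), C3 (2.37), Itgam (1.60) and Mmp19 (3.11) rose. Among glycolytic genes Slc16a3 (2.26), Pkm (2.05; 142 to 595 CPM), Slc2a1 (1.89) and Pfkfb3 (1.85) rose. Ifitm1 (3.89) and Hp (3.08) rose as well, with ambient limits of 32% and 59%.

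Resident identity, proliferation and ribosomal genes fell in macrophage-like cells. Of the resident dural macrophage list 3 of 31 rose and 17 fell (6 and 18 adjusted over the list alone, median −0.69, camera adjusted p = 0.000122), and this list had adjusted p = 0.414 with an estimated correlation. Cd209g (−3.05), Cd209f (−2.52; 671 to 112 CPM) and Igf1 (−2.26; 398 to 79.6 CPM) fell. Other members, Cd163 and Lyve1, were still among the leading genes of the main infected macrophage cluster when it was compared with all clusters. Of the cell cycle list 0 of 33 rose and 24 fell (0 and 25 adjusted over the list alone, median −1.10, adjusted p = 4.8e-08), with Top2a (−1.98) and Stmn1 (−1.37) among them. With mixed clusters not split, Top2a reversed to 0.61 and Stmn1 lost its call. Of the dissociation stress list 4 of 28 rose and 16 fell (4 and 17 adjusted over the list alone, median −0.45, adjusted p = 0.00045), including Klf4 (−1.51), Fosb (−1.24) and Nr4a1 (−0.99). Both of these lists had adjusted p = 0.27 with an estimated correlation. The cell cycle result depended on which proliferating cluster was named. A proliferating cluster of 106 control and 2 infected cells counted as macrophage-like, and the unnamed proliferating cluster of 4 control and 46 infected cells did not. With both counted, 0 of 37 genes rose and 4 fell (median −0.18, adjusted p = 0.028, in a range of 7.2e-17 to 0.27 over all alternatives).

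Ribosomal protein genes fell in 78 of 83 and rose in 0 (0 and 80 adjusted over the list alone, median −0.60, camera adjusted p = 1.4e-30), and mitochondrial transcripts fell in 12 of 13 and rose in 1 (1 and 12 adjusted over the list alone, median −1.19, adjusted p = 1.0e-08) in macrophage-like cells. Both had adjusted p = 0.27 with an estimated correlation. Examples were Rps27 (−1.27), Rps29 (−1.26), mt-Nd3 (−2.12; 264 to 59.9 CPM) and mt-Nd4l (−1.49). Nuclear genes of oxidative phosphorylation rose in 6 of 40 and fell in 13 (6 and 13 adjusted over the list alone, median −0.13, adjusted p = 0.027), with adjusted p = 0.5 with an estimated correlation. Sdhd (−0.996) and Ndufb3 (−0.84) fell and Cycs (1.17) rose, and the list call ended without cluster 8 (adjusted p = 0.153, in a range of 3.2e-05 to 0.5). Unfolded protein response genes rose in 12 of 18 and fell in 3 (13 and 3 adjusted over the list alone, median 0.55, adjusted p = 0.0027), with adjusted p = 0.414 with an estimated correlation. Creld2 (1.57) and Pdia3 (1.06) rose and Dnajb9 (−0.95) fell.

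The other lists did not pass with camera in macrophage-like cells. Iron handling had 5 genes up and 8 down of 19 (8 and 8 adjusted over the list alone), and the positive median of 0.26 and mean of 0.24 went against the downward camera direction (adjusted p = 0.611). Its members Slc40a1, the iron exporter (−2.71; 145 to 20.8 CPM), and Ncoa4 (−1.61) fell. Arginine and polyamine metabolism had 4 up and 2 down of 10 (4 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.466), with Arg2 (4.02) and Ass1 (3.09) up. Phagocytosis and lysosome had 10 up and 8 down of 28 (10 and 9 adjusted over the list alone, median 0.04, adjusted p = 0.695), with Msr1 (1.49) up and Hexa (−0.92) and Stab1 (−0.89) down. Sex-linked transcripts had 1 down of 4, Ddx3y (−0.36), at an adjusted p of 0.486, and haemoglobin genes were not measured in any tested class. Markers of other cell types moved too. In macrophage-like cells 10 of 11 mature neutrophil markers (median 1.59) and 6 of 9 classical monocyte markers (2.16) rose, 5 of 6 cDC2 markers fell (−1.62), and of the macrophage markers themselves 9 of 17 fell and 2 rose (−0.55). Chil3 set the ambient limit of infected macrophage-like cells, with Hp, S100a9 and S100a8 also among the lowest class-to-ambient ratios. For these monocyte or neutrophil markers an ambient source was therefore not excluded.

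In classical monocyte-like cells, interferon, inflammatory and bacterial recognition genes rose, and MHC class II and ribosomal protein genes fell. Of 5423 genes tested with edgeR, 1297 rose and 1155 fell, 677 and 381 of them by at least 2-fold. Saa3 went from 6.73 ± 10.3 to 13300 ± 11220 CPM, a log2 fold change of 11.21 ± 1.14 (adjusted p = 3.3e-05). Upp1, the uridine phosphorylase gene (ENSMUSG00000020407, chromosome 11, 9118103 to 9136170, plus strand), had 0 UMIs in control and 8753 in infected cells, at least 178.5-fold (0 to 315 ± 218 CPM, adjusted p = 0.0080). Rasgrp1 (0 to 42.8 CPM) and Spint1 (0 to 37.4 CPM) were also absent in control cells, with at least 22.02-fold and 20.0-fold more in infected ones. Mmp14 had 1 control and 3689 infected UMIs, a ratio of 225.7 (95% counting interval 40.5 to 8916), and Wfdc21 had 2 and 6991, a ratio of 213.8 (59.2 to 1766). Acod1 (7.86; 2.62 to 799 CPM), Cd38 (7.05), Lcn2 (7.001; 8.87 to 1219 CPM) and Sdc4 (6.50) rose. Cd209a (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984, minus strand) fell by 7.44 log2 units, from 47.8 ± 38.3 to 0.221 CPM. The prostaglandin-degrading gene Hpgd (ENSMUSG00000031613, chromosome 8, 56294585 to 56321043, plus strand) fell by 5.14, from 339 ± 51 to 14.3 CPM. Mgl2 (−4.19), Pdlim1 (−4.18), Stxbp6 (−4.13), Amz1 (−4.09), Padi2 (−4.07), Clec4b1 (−3.81), Fcrls (−3.80) and Hes1 (−3.74) fell too. Of the tested genes 24.9% showed no overlap between the groups (chance 0.433%), 1339 of them among those that passed.

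Gene groups of classical monocyte-like cells followed those of macrophage-like cells in most cases. Type I interferon genes rose in 35 of 37 and fell in 0 (35 and 1 adjusted over the list alone, median 1.58, camera adjusted p = 2.0e-11). Interferon gamma genes rose in 27 of 27 (27 and 0 adjusted over the list alone, median 2.90, adjusted p = 1.1e-09). MHC class I genes rose in 12 of 15 and fell in 0 (13 and 0 adjusted over the list alone, median 1.13, adjusted p = 4.0e-06). Inflammatory genes rose in 28 of 36 and fell in 1 (30 and 1 adjusted over the list alone, median 1.48, adjusted p = 1.6e-07). Bacterial recognition genes rose in 17 of 28 and fell in 1 (17 and 1 adjusted over the list alone, median 1.34, adjusted p = 0.00081), and complement genes rose in 6 of 10 and fell in 0 (6 and 0 adjusted over the list alone, median 1.07, adjusted p = 0.0105). These 6 lists all had adjusted p = 0.257 with an estimated correlation. Cxcl10 (3.66), Serpina3g (5.76), Gbp4 (5.55), H2-Q6 (3.64), Ccl5 (5.93; 20.3 to 1531 CPM), Il1rn (4.71), Fpr1 (5.96), C5ar1 (2.95), Cfb (5.35; 25.4 to 1019 CPM) and C1qb (1.20) were among the risen genes.

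MHC class II genes of classical monocyte-like cells rose in 1 of 8 and fell in 6 (1 and 6 adjusted over the list alone, median −1.12, camera adjusted p = 0.016), with adjusted p = 0.317 with an estimated correlation. H2-Aa fell from 1453 ± 428 to 471 ± 223 CPM (−1.63), H2-Eb1 by 1.57 and H2-Ab1 by 1.31 log2 units. The MHC class II score of infected mouse 5, 7.95, lay within the control range of 7.74 to 8.06. Cluster 14.3, with H2-Aa among its leading genes, gave 74 control and 0 infected cells to this class. Whether the MHC class II fall follows that cluster was not tested. Glycolysis and hypoxia genes rose in 20 of 23 and fell in 0 (20 and 1 adjusted over the list alone, median 1.28, adjusted p = 0.000116), with adjusted p = 0.384 with an estimated correlation. Ero1l (2.73), Tpi1 (2.49), Pfkl (2.13) and Hif1a (2.10; 91.3 to 391 CPM) rose. Unfolded protein response genes rose in 11 of 18 and fell in 2 (12 and 2 adjusted over the list alone, median 0.85, adjusted p = 0.018), with adjusted p = 0.479 with an estimated correlation. Creld2 (1.82) and Hspa5 (1.28) rose. Oxidative phosphorylation genes fell in 18 of 40 and rose in 0 (0 and 19 adjusted over the list alone, median −0.23, adjusted p = 2.8e-05). Cell cycle genes fell in 3 of 5 and rose in 0 (0 and 3 adjusted over the list alone, median −0.82, adjusted p = 0.023). Resident macrophage genes rose in 2 of 19 and fell in 8 (2 and 8 adjusted over the list alone, median −0.57, adjusted p = 0.0105). Ribosomal protein genes fell in 78 of 82 and rose in 0 (0 and 79 adjusted over the list alone, median −0.88, adjusted p = 2.3e-37), and mitochondrial transcripts fell in 11 of 12 and rose in 0 (0 and 11 adjusted over the list alone, median −1.11, adjusted p = 1.1e-09). These 5 lists had adjusted p = 0.257 with an estimated correlation. Without a low-count filter the direction of classical monocyte oxidative phosphorylation (adjusted p = 0.345, range over all alternatives 4.7e-06 to 0.345) and cell cycle genes (0.74, range 0.0156 to 0.74) reversed. The MHC class II and resident macrophage lists lost their calls under that setting. Uqcrh (−1.06), H2afz (−1.41), Clec10a (−2.38), Rps27 (−1.52) and mt-Nd3 (−2.43) fell.

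Other lists did not pass in classical monocyte-like cells. Antimicrobial and acute-phase genes had 14 up and 5 down of 22 (14 and 5 adjusted over the list alone, median 1.32, adjusted p = 0.053). Leukocyte adhesion had 15 up and 4 down of 25 (15 and 6 adjusted over the list alone, median 1.01, adjusted p = 0.069), with Vcan (2.91) up and Cx3cr1 (−2.85) down. Dissociation stress had 6 up and 11 down of 25 (7 and 11 adjusted over the list alone, median −0.21, adjusted p = 0.08), with Klf4 (−1.99) and Klf2 (−1.23) down. Iron handling had 6 up and 2 down of 11 (6 and 2 adjusted over the list alone, median 1.04, adjusted p = 0.186), with Fth1 (2.00; 6606 to 26340 CPM) and Hmox1 (1.77) up. Phagocytosis and lysosome had 6 up and 5 down of 21 (6 and 5 adjusted over the list alone, median 0.19, adjusted p = 0.654), with Ctsd (1.67) and Ctsl (1.60) up. Arginine and polyamine metabolism had 3 up and 2 down of 9 (3 and 2 adjusted over the list alone), with a median of 0.49 and mean of 0.63 against a downward camera direction (adjusted p = 0.82), with Ass1 (3.93) up and Sat1 (−1.21) down. Sex-linked transcripts had 0 of 3 passing (adjusted p = 0.47). In these cells 7 of 10 mature neutrophil markers (median 2.17) and 6 of 10 of their own markers (0.99) rose, while 3 of 4 cDC2 markers (−3.28) and 4 of 7 non-classical monocyte markers (−1.18) fell. The neutrophil marker S100a9 had 1 of the lowest class-to-ambient ratios in the infected cells, so an ambient source of it was not excluded.

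In non-classical monocyte-like cells, interferon, MHC class I and MHC class II genes rose, and ribosomal protein and mitochondrial transcripts fell. Of 2981 genes tested with edgeR, 599 rose and 560 fell, 307 and 167 of them by at least 2-fold. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, minus strand) rose by 6.38 ± 0.37 log2 units, from 8.38 to 883 ± 250 CPM (adjusted p = 4.6e-10). Itga9 had 0 control and 575 infected UMIs, at least 34.7-fold, Mmp14 likewise at least 28.0-fold, and Saa3 0 and 2065, at least 124.6-fold with an ambient limit of 43%. Cfb had 2 and 2136 UMIs, a ratio of 193.4 (95% counting interval 53.5 to 1598), and Ass1 3 and 1080, a ratio of 65.2 (22.2 to 316.6). Ratios of Spon1, Upp1, Serpina3g and Ifi205, each with 1 to 3 control UMIs, were 125.3 (22.4 to 4956), 100.3 (17.9 to 3969), 105.4 (36.0 to 511.8) and 84.5 (28.9 to 410.3). Gbp5 rose by 5.41. Fabp4, a fatty acid binding protein gene (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576, minus strand), fell from 693 ± 176 to 82.2 ± 60.6 CPM (−3.24) and Hpgd from 856 to 77.2 CPM (−3.42). G0s2 (−3.97), Olr1 (−3.33), Pf4 (−3.15), Ramp1 (−3.06), Cd83 (−3.03), Mef2c (−2.95), Cxcr4 (−2.90) and Setbp1 (−2.66) fell too. Of the tested genes 23.1% showed no overlap (chance 0.433%), 677 of them among those that passed.

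Most interferon genes of non-classical monocyte-like cells rose. In the type I interferon list 28 of 29 rose and 0 fell (28 and 0 adjusted over the list alone, median 2.50, camera adjusted p = 4.4e-13), in the interferon gamma list 21 of 21 rose (21 and 0 adjusted over the list alone, median 2.90, adjusted p = 2.7e-11), and in the MHC class I list 12 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.42, adjusted p = 9.3e-07). For these 3 lists the adjusted p was 0.212 with an estimated correlation. Ifit2 (4.90), Ifi47 (4.82), Gbp2 (5.16; 28.1 to 1005 CPM), Tap1 (2.66) and H2-Q6 (2.19) rose. MHC class II genes rose in 7 of 7 (7 and 0 adjusted over the list alone, median 1.73, adjusted p = 0.00058), with adjusted p = 0.279 with an estimated correlation. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, plus strand) went from 203 to 886 ± 474 CPM (2.10 ± 0.48, adjusted p = 0.0055) and Cd74 from 1669 to 5546 CPM (1.73, adjusted p = 0.0099), with overlap between the groups in both. The MHC class II score of infected mouse 1, 6.85, lay within the control range of 6.07 to 6.92. With Scrublet doublet calls kept, 4 of 8 MHC class II genes rose (median 0.67, adjusted p = 0.016, in a range of 1.2e-05 to 0.279 over all alternatives).

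The inflammatory score of infected mouse 5 lay within the control range in non-classical monocyte-like cells (6.58, controls 6.16 to 6.59). Inflammatory genes of these cells rose in 13 of 26 and fell in 1 (13 and 2 adjusted over the list alone, median 0.63, camera adjusted p = 0.0355), with adjusted p = 0.704 with an estimated correlation. Bacterial recognition genes rose in 11 of 22 and fell in 2 (13 and 2 adjusted over the list alone, median 0.80, adjusted p = 0.0367), with adjusted p = 0.6 with an estimated correlation. Complement genes rose in 5 of 9 and fell in 0 (5 and 0 adjusted over the list alone, median 1.02, adjusted p = 0.048), with adjusted p = 0.263 with an estimated correlation. In non-classical monocyte clusters the complement call ended with ambient counts subtracted (adjusted p = 0.0528) and its direction reversed with Scrublet calls kept (0.996), in a range of 0.0148 to 0.996 over all alternatives. The inflammatory call ended with ambient counts subtracted (0.0521, range 2.3e-08 to 0.704) and the bacterial recognition call with Scrublet calls kept (0.151, range 1.6e-06 to 0.6). Glycolysis and hypoxia genes rose in 6 of 15 and fell in 0 (6 and 0 adjusted over the list alone, median 0.40, adjusted p = 0.0102), with adjusted p = 0.285 with an estimated correlation. Acod1 (5.39), Fpr1 (3.89), C3 (1.87), Cfp (1.87), Hif1a (1.38) and Tpi1 (1.03) rose, and the fatty acid receptor gene Cd36 (−2.16) fell. Cell cycle genes fell in 3 of 4 and rose in 0 (0 and 3 adjusted over the list alone, median −0.85, adjusted p = 0.0355), with adjusted p = 0.209 with an estimated correlation. Dissociation stress genes rose in 4 of 25 and fell in 13 (4 and 15 adjusted over the list alone, median −0.52, adjusted p = 8.1e-05). Ribosomal protein genes fell in 72 of 80 and rose in 0 (0 and 74 adjusted over the list alone, median −0.63, adjusted p = 1.3e-35), and mitochondrial transcripts fell in 11 of 11 (0 and 11 adjusted over the list alone, median −1.34, adjusted p = 6.2e-13). These 3 lists had adjusted p = 0.172 with an estimated correlation. H2afz (−1.09), Egr1 (−2.51), Klf4 (−1.92), Rps27 (−1.53) and mt-Nd3 (−2.37) fell.

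Lists that did not pass in non-classical monocyte-like cells included antimicrobial and acute-phase genes, with 8 up and 4 down of 18 (9 and 4 adjusted over the list alone, median 0.32, adjusted p = 0.771), where Lyz2 fell (−1.69; 12590 to 3907 CPM). Resident macrophage genes had 1 up and 3 down of 9 (1 and 4 adjusted over the list alone, median −0.76, adjusted p = 0.358), oxidative phosphorylation 3 up and 9 down of 35 (3 and 8 adjusted over the list alone, median −0.05, adjusted p = 0.459), and iron handling 5 up and 2 down of 10 (5 and 2 adjusted over the list alone, median 0.29, adjusted p = 0.384). Phagocytosis had 4 up and 3 down of 19 (4 and 3 adjusted over the list alone, median 0.30, adjusted p = 0.459). For 3 lists the mean and median differed in sign. These were leukocyte adhesion, with 4 up and 6 down of 15 (5 and 6 adjusted over the list alone, median −0.16, mean 0.13, camera downward, adjusted p = 0.187), arginine metabolism, with 1 up and 3 down of 5 (1 and 3 adjusted over the list alone, median −0.33, mean 0.63, downward, adjusted p = 0.41), and the unfolded protein response, with 3 up and 3 down of 16 (3 and 3 adjusted over the list alone, median 0.08, mean −0.10, downward, adjusted p = 0.804). Cx3cr1 (−2.23; 461 to 99.1 CPM) and Ccr2 (−2.37) fell. Sex-linked transcripts, with 2 measured and 0 passing, were too few for a list test. Of their own markers 7 of 10 fell (median −0.85), and of classical monocyte markers 3 of 7 rose and 2 fell (0.84).

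**Figure D2:**
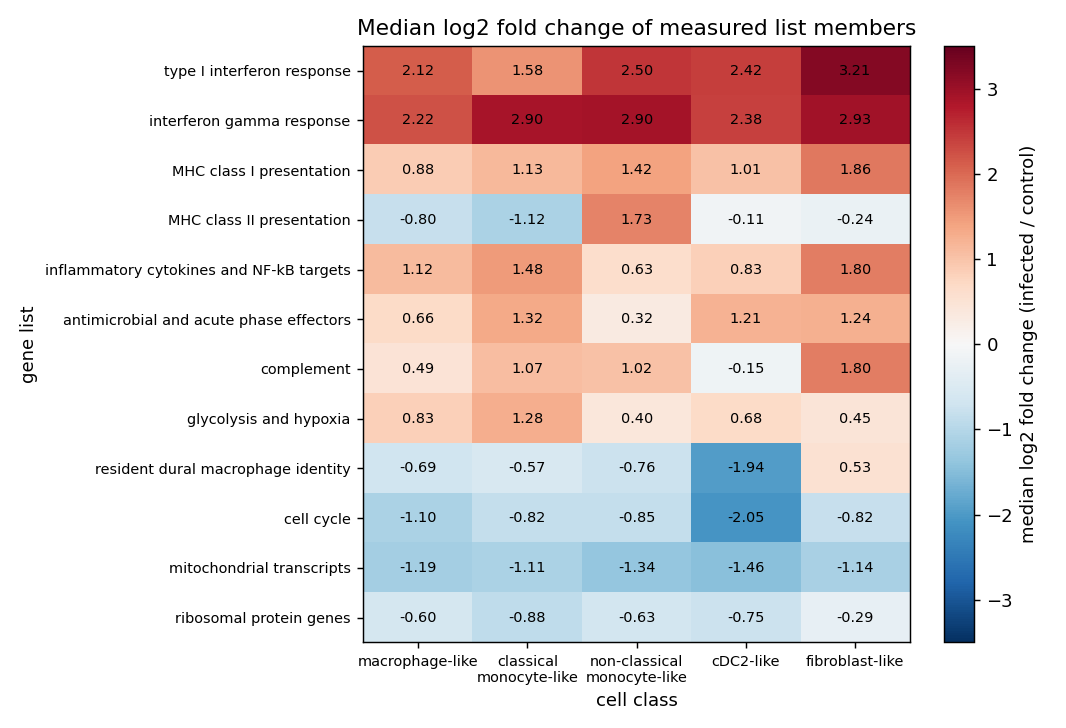
Median log2 fold change, infected over control, of 12 gene lists (vertical) in the 5 tested classes (horizontal), printed in each cell of the heat map without error bars. The interferon gamma list ranged from 2.22 in macrophage-like to 2.93 in fibroblast-like cells, while mitochondrial transcripts were lower in all 5 classes.

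In cDC2-like cells, interferon genes rose, and markers shared with macrophages and cell cycle genes fell. Of 5121 genes tested with edgeR, 1133 rose and 1091 fell, 583 and 446 of them by at least 2-fold. The oxysterol hydroxylase gene Cyp7b1 (ENSMUSG00000039519, chromosome 3, 18071950 to 18243338, minus strand) went from 0 to 137 ± 20 CPM, with 0 control and 208 infected UMIs, at least 118.2-fold (adjusted p = 1.3e-08). Spon1 (7.88; 2.42 to 466 CPM), Ifitm1 (6.72; 18.7 to 2071 CPM) and Ly6i (6.42) rose, and Slfn4 rose from 2 to 148 UMIs, a ratio of 126.2 (95% counting interval 34.3 to 1052). Fcrls fell from 374 UMIs to 3, a ratio of 73.1 control over infected (24.8 to 356.1). Igfbp4 fell from 154 to 1 (90.3; 15.97 to 3590), Cd209f from 177 to 2 (51.9; 14.2 to 431.9), Lpl from 157 to 2 (46.0; 12.53 to 383.5) and Il1rl1 from 149 to 2 (43.7; 11.9 to 364.1). Of macrophage markers 11 of 13 fell (median −2.26), of classical monocyte markers 4 of 5 rose (2.98), of migratory DC markers 3 of 3 rose (3.23), of mature neutrophil markers 3 of 6 rose (1.38), and of their own markers 2 rose and 5 of 11 fell (−0.45). Immature neutrophil markers (0.973) and pDC markers (1.065) rose in 3 of 3 each. Chil3 set the ambient limit of infected cDC2-like cells, with Lcn2 and S100a9 also among the lowest ratios. An ambient source of such monocyte and neutrophil markers was not excluded. Of the tested genes 25.4% showed no overlap between groups (chance 0.433%), 1287 of them among those that passed.

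Gene groups of cDC2-like cells again included interferon. Type I interferon genes rose in 35 of 36 and fell in 0 (36 and 0 adjusted over the list alone, median 2.42, camera adjusted p = 2.4e-16), with adjusted p = 0.227 with an estimated correlation. Interferon gamma genes rose in 25 of 26 and fell in 0 (25 and 0 adjusted over the list alone, median 2.38, adjusted p = 5.8e-12), MHC class I genes in 14 of 15 (14 and 0 adjusted over the list alone, median 1.01, adjusted p = 7.0e-08) and antimicrobial genes in 9 of 15 with 1 down (12 and 2 adjusted over the list alone, median 1.21, adjusted p = 0.0019). These 3 lists had adjusted p = 0.205 with an estimated correlation. The antimicrobial call ended with ambient counts subtracted. Inflammatory genes rose in 17 of 31 and fell in 4 (17 and 4 adjusted over the list alone, median 0.83, adjusted p = 0.0024), with adjusted p = 0.556 with an estimated correlation. Infected mouse 5 scored 6.54 for this list, within the control range of 5.79 to 6.65. Glycolysis and hypoxia genes rose in 9 of 20 and fell in 0 (10 and 0 adjusted over the list alone, median 0.68, adjusted p = 0.0023), with adjusted p = 0.38 with an estimated correlation. Resident macrophage genes rose in 1 of 22 and fell in 16 (1 and 16 adjusted over the list alone, median −1.94, adjusted p = 1.3e-06). Oxidative phosphorylation genes fell in 26 of 39 (0 and 27 adjusted over the list alone, median −0.52, adjusted p = 9.9e-08), mitochondrial transcripts in 11 of 11 (0 and 11 adjusted over the list alone, median −1.46, adjusted p = 1.7e-10) and ribosomal protein genes in 78 of 82 (0 and 79 adjusted over the list alone, median −0.75, adjusted p = 1.1e-37). Cell cycle genes fell in 22 of 25 and rose in 0 (0 and 24 adjusted over the list alone, median −2.05, adjusted p = 1.3e-10). The last 5 lists had adjusted p = 0.205 with an estimated correlation. The cDC2 cell cycle result came from the proliferating cluster of 70 control and 2 infected cells. Without that cluster 1 gene rose and 1 of 6 fell (median −0.05, adjusted p = 0.621, in a range of 4.7e-28 to 0.621 over all alternatives).

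In cDC2-like cells 10 lists did not pass. MHC class II had 2 up and 4 down of 12 (2 and 4 adjusted over the list alone, median −0.11, adjusted p = 0.254), bacterial recognition 8 up and 5 down of 18 (8 and 5 adjusted over the list alone, median 0.84, adjusted p = 0.346), complement 3 up and 4 down of 11 (3 and 4 adjusted over the list alone, median −0.15, adjusted p = 0.448) and leukocyte adhesion 8 up and 4 down of 15 (9 and 4 adjusted over the list alone, median 0.47, adjusted p = 0.346). Iron handling had 3 up and 4 down of 12 (median −0.18, adjusted p = 0.471), arginine metabolism 3 up and 2 down of 7 (0.04, 0.538), phagocytosis 4 up and 8 down of 22 (−0.33, 0.149) and the unfolded protein response 3 up and 4 down of 18 (−0.25, 0.346), each with the same counts adjusted over the list alone. Dissociation stress genes, with 7 up and 6 down of 25 (7 and 7 adjusted over the list alone), had a median of 0.04 and a mean of −0.0075 (adjusted p = 0.976). Sex-linked transcripts had 0 of 3 passing (adjusted p = 0.414).

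In fibroblast-like cells, which the CD45+CD11b+ gate should exclude, interferon and inflammatory genes rose and mitochondrial transcripts fell, on 3 control and 3 infected mice with 104 and 126 cells. Of 5250 genes tested with edgeR, 355 rose and 218 fell, 337 and 161 of them by at least 2-fold. The lubricin gene Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165, minus strand) had 1 control and 2087 infected UMIs, a ratio of 1443 (95% counting interval 258.7 to 57020; adjusted p = 0.026). C3 had 2 and 663, a ratio of 229.2 (63.2 to 1896), Cxcl1 1 and 309, a ratio of 213.6 (38.1 to 8465), and Serpina3n 0 and 421, at least 97.0-fold. Chil1 rose by 6.06 log2 units (adjusted p = 0.046). Trdn (ENSMUSG00000019787, chromosome 10, 33080554 to 33476709, plus strand) fell from 85 UMIs to 1, a ratio of 122.9 (21.5 to 4913), and the cartilage matrix genes Matn4 and Cilp2 fell from 325 to 34.6 CPM (−3.28) and from 149 ± 16 to 14.9 ± 8.4 CPM (−3.33 ± 0.38). Nppc (−3.35) and Nrep (−3.35) fell. The counts hung on single mice. They dropped to 10 up and 5 down without control mouse 6, and 5 up genes (Prg4, C3, Cxcl1, Serpina3n and Chil1) with Nppc and Nrep lost their call when some control mouse was left out, unlike Trdn, Matn4 and Cilp2. Of the tested genes 33.8% showed no overlap, where chance gives 10%, 571 of them among those that passed.

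Type I interferon genes of fibroblast-like cells rose in 22 of 24 (23 and 0 adjusted over the list alone, median 3.21, camera adjusted p = 9.3e-15), interferon gamma genes in 12 of 22 (21 and 0 adjusted over the list alone, median 2.93, adjusted p = 1.3e-10) and MHC class I genes in 9 of 13 (13 and 0 adjusted over the list alone, median 1.86, adjusted p = 5.3e-08), with 0 down in each. Mitochondrial transcripts fell in 10 of 13 (0 and 10 adjusted over the list alone, median −1.14, adjusted p = 1.9e-09). These 4 lists had adjusted p = 0.29 with an estimated correlation. Inflammatory genes rose in 7 of 17 (10 and 0 adjusted over the list alone, median 1.80, adjusted p = 3.9e-05), with adjusted p = 0.312 with an estimated correlation. Antimicrobial genes rose in 4 of 10 (7 and 0 adjusted over the list alone, median 1.24, adjusted p = 0.00056), complement genes in 5 of 9 (6 and 0 adjusted over the list alone, median 1.80, adjusted p = 0.0017), resident macrophage genes in 5 of 15 (6 and 0 adjusted over the list alone, median 0.53, adjusted p = 0.0137) and iron handling genes in 2 of 12 (5 and 0 adjusted over the list alone, median 1.22, adjusted p = 0.0053). Oxidative phosphorylation genes fell in 7 of 39 (0 and 11 adjusted over the list alone, median −0.47, adjusted p = 6.5e-07). These 5 lists had adjusted p = 0.196 with an estimated correlation. Dissociation stress genes rose in 2 of 25 (2 and 0 adjusted over the list alone, median 0.57, adjusted p = 0.00022), with adjusted p = 0.42 with an estimated correlation. Ribosomal protein genes fell in 8 of 82 (0 and 2 adjusted over the list alone, median −0.29, adjusted p = 2.2e-06), with adjusted p = 0.509 with an estimated correlation.

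Without passing in fibroblast-like cells, glycolysis had 1 up of 17 (median 0.45, adjusted p = 0.116), cell cycle 0 of 4 (−0.82, 0.137), leukocyte adhesion 0 of 7 (1 up adjusted over the list alone, 0.71, 0.333), arginine metabolism 2 up of 6 (3 and 0 adjusted over the list alone, 0.64, 0.34) and the unfolded protein response 2 up of 18 (0.34, 0.061). Counts without a second value were the same adjusted over the list alone. For 3 lists the mean or test differed in sign from the median. MHC class II had 0 of 8 passing (median −0.24, mean −0.09, camera upward, adjusted p = 0.754), phagocytosis 2 up and 1 down of 19 (median −0.03, mean 0.18, upward, adjusted p = 0.66) and sex-linked transcripts 0 of 3 (median −0.05, mean 0.19, upward, adjusted p = 0.545). Bacterial recognition had 2 of 2 up and was too small for a list test. Of classical monocyte markers 3 of 4 rose in these cells (median 1.85), and 3 of 8 of their own markers fell (−0.75). S100a9 set the ambient limit of infected fibroblast-like cells, with S100a8 and the monocyte marker Chil3 next lowest. An ambient source of such markers was not excluded.

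**Figure D3:**
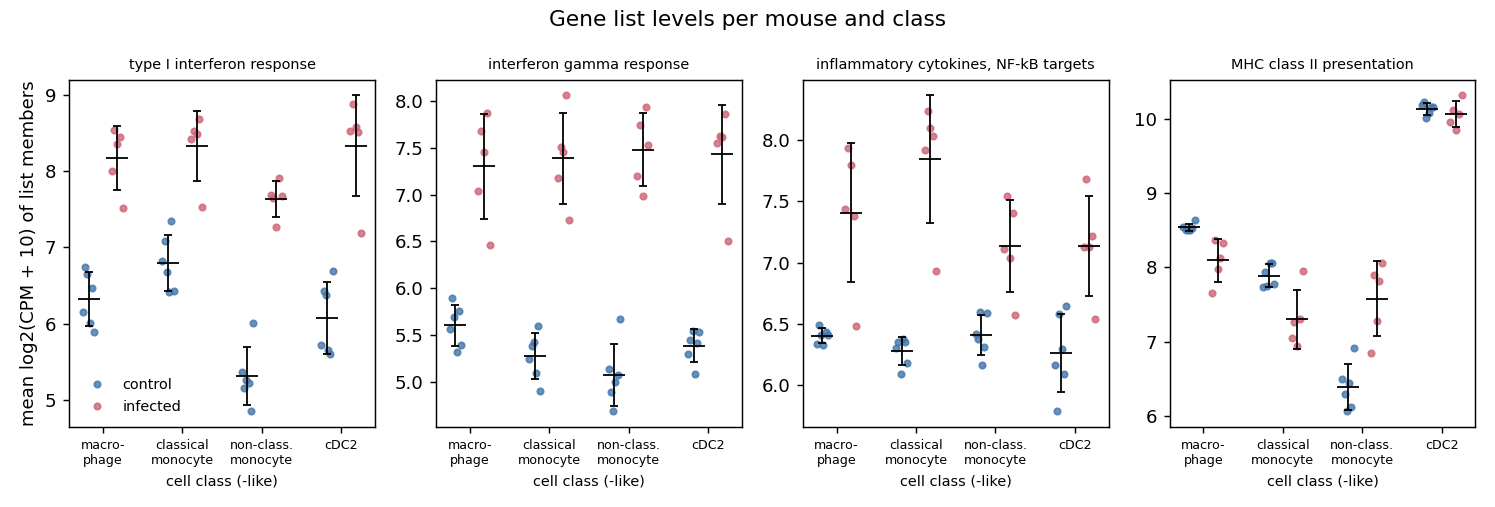
Mean log2(CPM + 10) of the members of 4 gene lists (y axis) in each of 4 classes, points being mice and bars the mean with SD for 6 control and 5 infected mice. Infected mouse 5 had the lowest type I interferon score of the infected group in classical monocyte-like cells, 7.53, and in cDC2-like cells, 7.19.

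The third question was whether classes responded to different extents. Interferon gamma and inflammatory genes rose more in classical monocyte-like than in macrophage-like cells. On mean log2(CPM + 10), interferon gamma genes rose by 1.70 in macrophage-like and 2.11 in classical monocyte-like cells, a difference of −0.41, and inflammatory genes by 1.01 and 1.57, a difference of −0.56. Both had an exact two-sided permutation p of 0.00217, the smallest possible over 462 splits, with n = 6 and 5 (adjusted p = 0.00433). The differences in type I interferon genes (0.32, exact permutation p = 0.0584) and MHC class II genes (0.14, exact permutation p = 0.351) did not pass. The type I interferon difference passed without control mouse 3 (0.41, exact permutation adjusted p = 0.0317) and without infected mouse 1 (0.39, 0.0444), in a range of 0.0317 to 0.159 over all alternatives. In comparisons added after the data were seen, MHC class II genes changed by −0.45 in macrophage-like cells, 1.19 in non-classical monocyte-like cells and −0.07 in cDC2-like cells. The differences from macrophage-like cells, −1.63 and −0.37, each had the smallest possible exact permutation p, 0.00217 (adjusted p = 0.00866, n = 6 and 5). With Scrublet calls kept, MHC class II genes changed by 0.58 in non-classical monocyte-like cells and the difference was −1.02. Against non-classical monocyte-like cells, macrophage-like cells differed by −0.47 in type I interferon (exact permutation adjusted p = 0.255), −0.70 in interferon gamma (0.104) and 0.28 in inflammatory genes (0.159). Against cDC2-like cells the differences were −0.41 (0.24), −0.35 (0.0577) and 0.13 (0.50), from exact permutation. At CPM + 1 the interferon gamma differences from non-classical monocyte-like and from cDC2-like cells passed. The drop in macrophage MHC class II relative to cDC2-like cells was −0.045 without macrophage cluster 8 (exact permutation p = 0.742).

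Ambient RNA was a small part of most profiles. Its upper limit was 1.09% of control and 2.12% of infected macrophage-like UMIs, 0.910% and 1.504% in classical monocyte-like cells, 0.851% and 2.08% in non-classical monocyte-like cells, 0.827% and 1.75% in cDC2-like cells and 0.733% and 1.58% in fibroblast-like cells. Mature neutrophil-like cells had limits of 11.0% in control and 3.47% in infected mice.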

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

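Each group of mice was searched for a single mouse far from the others, a search that marks about 1 in 20 groups by chance. Of 552 groups of named-gene values 59 held such a mouse, where chance gives 27.6, and of 68 other groups 6 did, where chance gives 3.4. Infected mouse 5 was the mouse apart in 31 of them, and no mouse was removed. Control mouse 2 stood apart in cells kept, with 742. Control mouse 6 had the MHC class II score apart in macrophage-like cells, 8.639. Infected mouse 5 stood apart with low type I interferon scores in classical monocyte-like cells (7.532) and cDC2-like cells (7.189), a low inflammatory score in classical monocyte-like cells (6.93) and a low interferon gamma score in cDC2-like cells (6.506).

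In macrophage-like cells infected mouse 5 was far below the others in Acod1 (18.03 CPM), Jaml (20.34), Oas3 (37.99), Cd274 (33.38) and C3 (27.63), and apart in Ndufb3 (77.51). Control mouse 1 stood apart in Spon1 (1.907 CPM), control mouse 3 in Lpl (101), infected mouse 1 in Marco (233.3) and infected mouse 4 in H2afz (321.3).

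In classical monocyte-like cells infected mouse 5 stood apart in most of the marked genes. Among rising genes its values were Cd38 123.5, Sdc4 78.51, Oasl1 73.27, Ifit2 109.9, H2-Q4 62.81, Il1rn 18.84, Sod2 196.8, Fpr1 39.78, Fpr2 65.95, C3 137.1, Hif1a 185.3, Arg2 59.67 and Msr1 125.6 CPM. Among falling genes they were Hpgd 47.1, Padi2 12.56, Pf4 54.43, Cx3cr1 70.13 and Sat1 758.9 CPM. Other mice apart were control 3 in Wfdc21 (7.237), control 2 in Mmp14 (4.358), control 4 in Mgl2 (84.38) and Hif1a (52.74), control 5 in Gbp6 (34), control 6 in Hspa5 (553), infected 4 in Pcna (33.32) and infected 2 in Hmgb2 (354.9).

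In non-classical monocyte-like cells control mouse 6 stood apart in Spon1 (10.52 CPM), Serpina3g (31.57), Ifi205 (31.57), Gbp2 (126.3), Iigp1 (105.2), Ccl5 (136.8), Sod2 (378.8) and Hp (610.3). Control mouse 5 did so in Fpr2 (0), C3 (0), Hmgb2 (280.7) and Zfp36 (1057), and control mouse 3 in H2-Q6 (0) and Blvrb (43.6). Single values were Cfb in control mouse 1 (14.55) and infected mouse 5 (362.8), Upp1 in control mouse 4 (11.04), Ifi47 in control mouse 2 (0), and Pcna (116.9) and Rps27 (860.9) in infected mouse 1. In cDC2-like cells infected mouse 5 stood apart in Igfbp4 (1.588) and Cd209f (3.177), and control mouse 2 in Cd209f (5.402).

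Differences in response between classes that passed correction were also looked at. Macrophage-like cells differed from classical monocyte-like cells by −0.4148 in interferon gamma and −0.5606 in inflammatory genes. In MHC class II genes they differed by −1.631 from non-classical monocyte-like cells and by −0.3712 from cDC2-like cells.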

How the results depend on the processing

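Most alternative settings were fixed in advance, and those on low-UMI clusters, cluster splitting, macrophage cluster 8, the proliferating clusters and the added class pairs were chosen after the result was seen. The causes of changed values were not tested. Control cells kept were 6563 at 1000 UMIs, 7262 at a mitochondrial maximum of 5%, 9032 with Scrublet calls kept and 10055 with the fixed tag margin, and infected cells 7581, 9006, 9325 and 10235. Of the class shares 202 comparisons were the same and 8 reversed. At resolution 0.5 the differences for cDC2-like (−0.569), osteoclast-like (−0.377) and migratory DC-like cells (2.41) passed, but the cDC2 and migratory DC names then covered other cells. Osteoclast-like cells hardly changed, with 42 control and 7 infected cells against 43 and 7 in the main clustering. The only cDC2 cluster was a proliferating one of 53 control and 4 infected cells, while a cluster led by MHC class II genes and Cd209a (1144 and 151) stayed unnamed, and migratory DC-like cells numbered 56 and 277. On the classes of the report, each of the 3 passed without 1 mouse, cDC2-like without infected 5 (exact permutation adjusted p = 0.0419), osteoclast-like without control 2 (0.0175) and migratory DC-like without infected 2 (0.0210). Among class shares, immature neutrophil-like cells differed by −3.04 with tags ignored, −1.48 with Scrublet calls kept (exact permutation p = 0.0281, adjusted p = 0.0556), −1.71 with mixed clusters not split, −1.03 without infected 5 and −0.413 without infected 4. Neutrophil progenitor-like cells differed by 0.195 without infected 5 and 0.412 without infected 3. The fibroblast-like difference reversed at 1000 UMIs (−0.121) and outside the low-UMI clusters (−0.138). Leaving out mice, the fibroblast-like difference ran from −0.297 (without infected 1) to 0.319 (control 6), cDC2-like from −2.06 (infected 5) to −1.13 (control 1), osteoclast-like from −0.478 (control 2) to −0.316 (control 3), migratory DC-like from 0.409 (infected 1) to 0.842 (infected 2) and endothelial-like from −0.0506 (infected 1) to 0.0125 (infected 4).

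Macrophage-like cells had 1480 genes up and 1239 down with at most 100 cells per mouse, and non-classical monocyte-like cells 1122 up without a low-count filter. Fibroblast-like counts moved most, to 769 up and 377 down without a filter, 606 and 585 with the fixed margin and 132 down with the DESeq2 Wald test. Without control mouse 6 they were 10 and 5, and without infected mouse 5 724 and 481. Named genes kept their call in 6315 comparisons and lost it in 127. Top2a reversed in macrophage-like cells with mixed clusters not split (0.61), where H2-Aa, H2-Ab1, H2-Eb1 and Stmn1 lost their calls. That setting also left cluster 8 out of the macrophage-like cells. Slc7a1 in non-classical monocyte-like cells ran from −1.05 (without control 6) to 0.0541 (without control 1). H2-Q6 in macrophage-like cells lost its call with at most 100 cells, without a filter and without infected 1 or 3, and Ddx3y with at most 100 cells.

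With an estimated correlation in camera 0 lists passed in each of the 5 classes. With fry, which tests a list without comparing it with other genes, the camera calls held except for MHC class II in macrophage-like (adjusted p = 0.0858), the unfolded protein response in classical monocyte-like (0.0862), and inflammatory (0.276) and bacterial recognition genes (0.128) in non-classical monocyte-like cells. In fibroblast-like cells fry did not pass interferon gamma (0.0777), MHC class I (0.0722), inflammatory (0.136), dissociation stress (0.174) and ribosomal protein genes (0.106). Some macrophage-like lists that camera did not pass had a fry adjusted p below 0.05. These were iron handling (0.0165), arginine and polyamine metabolism (0.0397) and sex-linked transcripts (0.0101). The MHC class II list of macrophage-like cells turned upward with mixed clusters not split (adjusted p = 0.981) and lost its call without control 6, infected 3 or infected 5. Not splitting the mixed clusters also left cluster 8 unnamed, so its effect cannot be told apart from leaving that cluster out. Without a low-count filter, oxidative phosphorylation (0.345) and cell cycle (0.74) reversed in classical monocyte-like cells, and the MHC class II and resident macrophage lists lost their calls. With Scrublet calls kept, complement in non-classical monocyte-like cells reversed (0.996) and bacterial recognition lost its call (0.151). Subtracting ambient counts ended complement (0.0528) and inflammatory genes (0.0521) in these cells and the antimicrobial list of cDC2-like cells (0.098). In fibroblast-like cells the resident macrophage list ended with Scrublet calls kept (0.0794) and without a filter (0.116).

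Between classes, the macrophage minus classical monocyte difference in MHC class II was −0.23 at CPM + 1, a reversal. At CPM + 1 interferon gamma differences passed against non-classical monocyte-like (−1.53) and cDC2-like cells (−0.55), and without cluster 8 the MHC class II difference from cDC2-like cells was −0.0452. Leaving out mice, type I interferon against classical monocyte-like cells ran from 0.24 (control 5) to 0.41 (control 3) and against cDC2-like cells from −0.61 (control 6) to −0.28 (control 5). Interferon gamma against non-classical monocyte-like cells ran from −0.865 (infected 3) to −0.48 (infected 5) and against cDC2-like cells from −0.42 (control 6) to −0.25 (infected 1). With ambient profiles of at most 50 UMIs the limits were 0.971% and 1.80% in control and infected macrophage-like, 2.27% in infected classical monocyte-like, 1.58% in infected non-classical monocyte-like and 1.20% in infected fibroblast-like cells.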

Other observations

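Levels of cytokine genes in cells without a gene test fill in part of the picture. Mature neutrophil-like cells of infected mice (n = 5) carried 14740 ± 2757 CPM of Il1b, 23380 ± 6834 of the chemokine gene Cxcl2 and 4661 ± 1711 of Acod1. In the 2 control mice with enough of these cells the levels were 2436 ± 83, 2920 ± 1515 and 419.5 ± 219.7. Among granule genes, Camp was 54.7 CPM in infected and 5528 in control cells, and Ltf 18.9 and 1035. This gap, and those in Il1b, Cxcl2 and Acod1, may follow which cluster was named mature, which was not tested. Control cells came mostly from a cluster split off the immature neutrophils, with Ngp and Camp among its leading genes, and their ambient limit was 11.0%. Without that split mature neutrophil-like cells were 0.145% of control cells. The class was not tested because of the 2 control mice. Il1a was 535 and Cxcl3 119 CPM in infected mature neutrophil-like cells, and both were 0 in control ones.

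Cytokine levels in other classes were read without a test. Migratory DC-like cells of 3 infected mice had the highest Ccl5, 13000 ± 4679 CPM, and Il12b at 232 ± 143. Fibroblast-like cells of 3 infected mice had Ccl2 at 1498 ± 2181 CPM against 22.8 in controls, and Il6 at 125 and Csf3 at 137 against 0. Their SD exceeded the mean. Nos2 was 243 ± 165 CPM in infected classical monocyte-like cells and 0 in control ones.

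Chance regrouping was tested, after the results were seen, by mixing the mice of both groups in 100 random splits per class. The real split was the only 1 of 100 with as many genes in macrophage-like (5028, highest other 3436), classical monocyte-like (2452 and 1754), non-classical monocyte-like (1159 and 720) and cDC2-like cells (2224 and 1373). Each highest other exchanged 5 mice, so it kept the real groups apart except for 1 control mouse placed with the infected ones. Splits of these classes that exchanged 2 to 4 mice gave at most 1 gene. For fibroblast-like cells the 10 possible splits are too few, with 573 genes in the real one, 1 of 10, and at most 0 in another. These splits cannot tell infection from library. Of the tests that follow, the library difference and both Saa3 tests were also written after the result was seen, the others before.

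The first pattern was the fall of mitochondrial transcripts in all 5 tested classes and of ribosomal protein genes, most clearly in 4 of them. In fibroblast-like cells only 8 of 82 ribosomal protein genes fell. Their list passed downward there in camera with the preset correlation, but not with fry. A few genes taking most counts would shift all others by only −0.0062 log2 units, against a ribosomal median of −0.60 in macrophage-like cells, and with ambient counts subtracted that median was −0.62. In macrophage-like ribosomal genes both argue against these explanations, and these 2 values leave mitochondrial transcripts and the other classes open. The mitochondrial medians differed by 0.35 between classes, so a difference between the 2 libraries, shared by all classes, remains possible and cannot be separated from infection.

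The second pattern was Saa3 in infected macrophage-like cells. Ambient RNA could supply at most 4.11% of it. Abundant classical monocyte markers stood at a median of 2.06% of their level in classical monocyte-like cells, against 63.0% for Saa3, so monocytes counted as macrophages are unlikely to be the source. Single markers were higher, with Ccr2 at 19.4% and Mgst1 at 34.4%. The wording of these 2 tests was changed after the result, and neutrophils as a source were not tested.

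The third pattern was the fall of MHC class II genes in macrophage-like cells. Without cluster 8 the median log2 fold change of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 was −0.49. That lies between the bounds set for a loss of that cluster and for a fall within cells. Fewer cells of cluster 8 may account for part of the fall, and the question stays open. Cluster 13, also led by H2-Eb1, H2-Aa and H2-Ab1 (185 control and 292 infected cells), was left out for its low UMI count. A loss of MHC-II-high cells as a whole was therefore not shown. With ambient counts subtracted the same median was −1.08, which argues against ambient RNA. A fresh pair of libraries with both groups in each would separate library from infection.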
